A study of Mus musculus with 16 samples.

How the data were processed

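The deposited values are FPKM made by the authors from poly-A RNA-seq, as the table's name and the processing notes state, and the values fit that unit. Per the labels, total RNA was purified on DirectZol columns, poly-A RNA was selected and cDNA was made with random hexamers. The submitters' processing notes name STAR, without a version, and FastQC 0.11.8. They name the builds mm10 and GRCm39 without saying which was used for what. The program and annotation that gave FPKM are not given in the sources used here. The table held 24346 rows of genes, of which 27 had symbols turned into dates by a spreadsheet and were left out as unnamed, and 7122 were 0 in every library. It held no mitochondrially encoded gene. Reads were not analysed here.

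Genes with a mean FPKM of at least 0.5 over the 16 libraries were tested (11802). Values were log2(FPKM+1), and no further scaling was applied. All 4 groups were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, 12 residual degrees of freedom), and contrasts gave the 4 pairwise comparisons and the interaction, (LKO ZT16 minus LKO ZT4) minus (WT ZT16 minus WT ZT4). A gene passed with a Benjamini-Hochberg adjusted p under 0.05. Tables and figures were made with Python 3.11.15 and matplotlib 3.10.9. Transcript lengths were medians over the GENCODE M21 transcripts of GRCm38 and were found for 96.3% of tested genes. FPKM without counts leaves the depth of a gene unknown, so precision was modelled from the mean alone.

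Of 40 gene lists fixed beforehand, 36 with at least 5 tested genes were tested with camera of limma at a preset correlation of 0.01 between genes, with adjustment over the 36 lists. A list counts as called by this test. The same lists were tested with camera at the correlation estimated from the residuals, with fry, and by exact permutation of the mean list score over libraries (70 assignments for a pair of groups). The smallest exact p of 70 assignments is 0.0286, which passes adjustment over 36 lists only if many lists share it. The preset correlation takes little account of libraries in which a whole list moves together: for ER folding genes the estimated correlation was 0.92. The lists not tested were mitochondrially encoded genes (0 of 13 in the table) and markers of blood cells (2 tested of 22), hepatocytes (0 of 22), and macrophages and endothelium (1 of 14). Genes of a list were also adjusted over the list alone.

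Genes named in the report were chosen by rule. From the genes that passed without overlap between groups (for the interaction, that passed), the 8 largest rises and 8 largest falls were named. Where fewer than 10 passed, the 5 higher and 5 lower genes with the smallest p were named as not passing. Up to 4 members with the smallest p of each described list were named, and core clock genes could be. Arntl was named in every comparison. Predicted genes were counted and not chosen, except that Gm12191 is named so that all 11 genes with an interaction are given.

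Relative depth was estimated per library from genes with low values, those with FPKM times transcript length below 150. One read adds a fixed step to FPKM times length, and the shift between libraries of that step was read from the mode of log2 ratios (bandwidth 0.02). Between 391 and 605 low genes were used per library, and 9.56 to 24.1% of ratios lay within 0.05 log2 of the mode.

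The alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 2 FPKM, scaling to the same summed FPKM, median-ratio scaling, library weights, a model of only the 2 groups compared, and leaving out each library. Added later were removal of a smooth trend of each library with transcript length (spline with 5 degrees of freedom), removal of length and GC trends together, only transcripts of at least 1000 nt, the exact permutation of list scores and the comparisons averaged over times or genotypes.

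The pipeline was tested on simulated values with the group structure, in which 50 genes per size were changed. Of genes changed by 0.25, 0.5, 1 and 2 log2, the fit found 24, 78, 94 and 100% in the comparison of WT ZT16 with WT ZT4, 28, 80, 94 and 100% in that of LKO ZT16 with WT ZT16, and 8, 42, 86 and 100% for the interaction, with 9, 5 and 8 false calls.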

Results

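The data were poly-A RNA-seq of C2C12 myotubes, a mouse muscle cell line, exposed for 24 hr to serum of mice bled at ZT4 (day) or ZT16 (night). The donors were wild-type (WT) mice or mice with a liver-specific deletion of Bmal1 (LKO). The 2 genotypes and 2 times made 4 groups of 4 libraries each, which the labels call biological replicates. All 16 libraries were used. Myotubes under WT ZT4 serum, WT ZT16 serum, LKO ZT4 serum and LKO ZT16 serum are called WT ZT4, WT ZT16, LKO ZT4 and LKO ZT16 here.

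Read counts per library were not used here. Depth relative to the deepest library, WT ZT4 replicate 2, was estimated from the smallest steps of the FPKM values. It was 85.7 ± 14.6% (mean ± SD, n = 4 in each group here and in the comparisons) in WT ZT4, 77.5 ± 8.96% in WT ZT16, 68.7 ± 3.78% in LKO ZT4 and 84.8 ± 11.9% in LKO ZT16. The shallowest library, LKO ZT4 replicate 2, had 65.6%. Between 14258 and 14901 genes had a value above 0 per library, and summed FPKM ran from 581966 to 691771. A short-minus-long value was taken per library, the mean log2(FPKM+1) of transcripts under 500 nt minus that of transcripts over 2000 nt, with each gene centred over libraries. LKO ZT4 was the least even group. The value was -0.07, 0.13, -0.13 and 0.23 in its replicates 1 to 4. It was -0.05 ± 0.02 in WT ZT4, 0.07 ± 0.05 in WT ZT16 and -0.05 ± 0.04 in LKO ZT16. LKO ZT4 replicate 1 lay apart on the leading principal component (17.2% of variance), at 22.2 against 11.4 for the next library.

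Arntl, the table's symbol for Bmal1, was expressed in all 16 libraries. Its FPKM in replicates 1 to 4 was 7.88, 7.50, 4.64 and 5.22 in WT ZT4 (6.31 ± 1.62), 5.53, 5.72, 5.28 and 4.87 in WT ZT16 (5.35 ± 0.365), 7.51, 4.82, 6.26 and 5.15 in LKO ZT4 (5.93 ± 1.21), and 6.29, 5.41, 4.25 and 4.35 in LKO ZT16 (5.07 ± 0.964). LKO minus WT was -0.07 ± 0.15 log2 (estimate ± SE) at ZT4 (adjusted p = 0.921) and -0.08 ± 0.15 at ZT16 (adjusted p = 0.867). Bmal1 was deleted in the liver of the serum donors and not in the myotubes, so Arntl in these libraries does not check the deletion.

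The 5 comparisons, the gene lists and most alternatives were fixed before the data were examined. Removal of trends with transcript length or GC content, the limit of 1000 nt, the block by column names and the exact permutations of list scores were added later. Gene changes are differences of log2(FPKM+1), a scale that understates the change of genes with low FPKM, and 11802 genes were tested. The p-values measure only the spread between these samples, which may be technical. WT ZT4, WT ZT16, LKO ZT4 and LKO ZT16 each enter 2 of the pairwise comparisons and the interaction, so these results are not independent of one another. Scaling every library to the same summed FPKM moves all genes of a library in 1 direction. It shifted the medians of the 36 gene lists by -0.08 to -0.04 in WT over time, 0.07 to 0.10 in LKO over time, -0.08 to -0.05 at ZT4, 0.07 to 0.11 at ZT16 and 0.10 to 0.19 in the interaction. A median that turned sign under it is therefore not read as a change of that list against other genes, and its list calls are given.

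Under WT serum, the question was which myotube transcripts differed between night and day serum. No gene passed, and those with the smallest p included ribosomal protein transcripts. Rps27rt, a retrogene copy of the ribosomal protein gene Rps27, had FPKM of 2875 ± 98.2 in WT ZT4 and 4964 ± 251 in WT ZT16. Snhg6, a small nucleolar RNA host gene, had 48.3 ± 5.09 and 73.9 ± 7.44. The ribosomal protein gene Rps21 had 1863 ± 223 and 3199.7 ± 219.7. Neat1, a noncoding RNA of nuclear paraspeckles, had 54.5 ± 17.5 and 28.6 ± 5.54. In each of these genes all 4 libraries of one group lay beyond all 4 of the other, as in 512 genes, 4.34% of those tested against 2.86% expected by chance.

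The smallest adjusted p were those of Rps27rt (0.79 ± 0.12, adjusted p = 0.0550, 0.000537 to 0.345 over the alternatives) and Snhg6 (0.60 ± 0.10, adjusted p = 0.0899). Next among higher values were Rps21 (0.79 ± 0.15, adjusted p = 0.244), Rpl34-ps1, a pseudogene of Rpl34 (0.59 ± 0.12, adjusted p = 0.313) and Rpl39 (0.51 ± 0.11, adjusted p = 0.423). Lower values not passing were those of Neat1 (-0.87 ± 0.21, adjusted p = 0.529), Tecrl, an ER protein of the enoyl reductase family (-0.42 ± 0.10, adjusted p = 0.568), the aldo-keto reductase Akr1b7 (-0.48 ± 0.12, adjusted p = 0.595). Further down were Chpt1, which makes phosphatidylcholine (-0.25 ± 0.06, adjusted p = 0.6004) and the adaptor Bcar3 (-0.25 ± 0.07, adjusted p = 0.864). In limma 468 genes had an unadjusted p under 0.05 where chance gives 590. With every library scaled to the same summed FPKM 1 gene passed, higher under night serum, as with at least 2 FPKM or the length trend removed, and 7 passed with library weights (6 higher) and 18 in a fit of only the 2 groups (17 higher). Values of Rps27rt, Rpl34-ps1 and the ribosomal protein genes are uncertain throughout, because such genes have near-identical copies and how reads that map to several places were counted is not given in the sources used here.

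Of 36 gene lists, 13 differed between WT ZT16 and WT ZT4, 8 higher and 5 lower, and 8 did without WT ZT16 replicate 1. None was called with an estimated correlation (adjusted p = 0.748, and 0.759 for hypoxia targets). Cytosolic ribosomal proteins rose as a group (median 0.15, 76 of 77 genes higher, adjusted p = 4.83e-35), among them Rps21, Rpl39, Rpl38 (0.84 ± 0.20) and Rpl37a (0.48 ± 0.12). When adjusted over the list alone, 8 of the 77 passed. Nuclear-encoded oxidative phosphorylation genes rose (median 0.14, 74 of 78, adjusted p = 2.74e-23, 2 passing over the list alone). They were led by the complex I subunit Ndufa3 (0.68 ± 0.15), the complex IV subunits Cox7a2 (0.36 ± 0.09) and Cox7a1 (1.14 ± 0.35) and the complex III subunit Uqcr10 (0.30 ± 0.09). Mean log2(FPKM+1) of the ribosomal list was 10.27 ± 0.06 in WT ZT4 and 10.46 ± 0.08 in WT ZT16, and of the oxidative phosphorylation list 7.60 ± 0.03 and 7.77 ± 0.06. Median annotated transcript length was 711.5 nt in the ribosomal list (12 of 77 under 500 nt) and 669.5 nt in the oxidative phosphorylation list (11 of 78), against 2106.75 nt for all tested genes. Among transcripts of at least 1000 nt the oxidative phosphorylation median was 0.04 (adjusted p = 0.000379). The short-minus-long value was 0.07 ± 0.05 in WT ZT16 and -0.05 ± 0.02 in WT ZT4.

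The other 6 higher lists under WT night serum had small medians and calls that depended on the libraries used. They were mitochondrial ribosomal proteins (0.04, adjusted p = 0.000831), the proteasome (0.03, adjusted p = 0.00899), glycolysis (0.11, adjusted p = 0.00899), TGF-beta targets (0.07, adjusted p = 0.0455), hypoxia targets (0.11, adjusted p = 0.0465) and SRF and actin genes (0.07, adjusted p = 0.0475). Without WT ZT16 replicate 1 the medians of glycolysis, hypoxia targets and mitochondrial ribosomal proteins were 0.05, 0.06 and 0.01 (adjusted p = 0.486, 0.505 and 0.337). Without WT ZT4 replicate 4 mitochondrial ribosomal proteins had 0.03 (adjusted p = 0.141), and without WT ZT4 replicate 2 they had 0.07. Without WT ZT4 replicate 1 glycolysis had 0.08 (adjusted p = 0.0874). The proteasome had 0.01 without WT ZT4 replicate 4 (adjusted p = 0.815), was lost without WT ZT16 replicate 1 or 4 (adjusted p = 0.184 and 0.0538), and had 0.06 without WT ZT4 replicate 2 and 0.05 without WT ZT16 replicate 2. Hypoxia targets were also lost without WT ZT4 replicate 1, 2 or 4 or WT ZT16 replicate 4 (adjusted p = 0.109, 0.0505, 0.148 and 0.216). TGF-beta targets were lost without WT ZT4 replicate 2, 3 or 4 or WT ZT16 replicate 2 or 3 (0.05, 0.03, 0.08, 0.04 and 0.05, adjusted p = 0.252, 0.166, 0.163, 0.481 and 0.389). SRF and actin genes were lost without the same 5 libraries (0.04, 0.06, 0.05, 0.06 and 0.03, adjusted p = 0.3096, 0.166, 0.262, 0.154 and 0.469), and had 0.11 without WT ZT4 replicate 1 and 0.10 without WT ZT16 replicate 1. With the same summed FPKM per library the proteasome (median -0.051, adjusted p = 0.989) and mitochondrial ribosomal proteins (-0.043, adjusted p = 0.0785) were lost, and TGF-beta targets (-0.012, adjusted p = 0.00877) and SRF and actin genes (-0.018, adjusted p = 0.0273) stayed called. Mitochondrial ribosomal proteins and glycolysis were lost among transcripts of at least 1000 nt (adjusted p = 0.0591 and 0.0781), and glycolysis with length and GC trends removed (adjusted p = 0.102). Of 12 settings other than a left-out library, hypoxia targets were lost under 6 (adjusted p up to 0.0839), SRF and actin genes under 3 (up to 0.136) and TGF-beta targets under 3 (up to 0.101).

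The 5 lists called lower under WT night serum were lost with an estimated correlation (adjusted p = 0.748) and by fry. As many lists were called by 17 of 35 groupings of the 8 libraries, the real one included. The exact permutation of list scores called 0, but its smallest possible p of 0.0286 leaves it little room to decide. ATF4 targets were lower (median -0.20, 36 of 36 genes lower, adjusted p = 9.96e-13), among them the mitochondrial folate enzyme Mthfd2 (FPKM 143 ± 25.0 in WT ZT4 and 122 ± 2.51 in WT ZT16), the stress cytokine Gdf15 (33.4 ± 13.8 and 20.5 ± 2.18) and the glutathione-degrading enzyme Chac1 (63.4 ± 44.5 and 34.9 ± 5.41). Without WT ZT4 replicate 2, in which Chac1 (129.7) and Gdf15 (53.8) stood far above the rest of the group, the ATF4 median was -0.09 (adjusted p = 0.00781). Cholesterol synthesis genes were lower (median -0.24, 25 of 25, adjusted p = 1.61e-09), including Fdps (207 ± 22.2 and 152 ± 35.4), Hsd17b7 and Idi1. PPAR targets (median -0.10, 21 of 24, adjusted p = 0.000343) were lower, with the lipid droplet coat Plin2 (-0.52 ± 0.20) and the pyruvate dehydrogenase kinase Pdk4 (-0.41 ± 0.21). ER folding genes (-0.23, 22 of 23, adjusted p = 0.000343) and fatty acid synthesis genes (-0.10, 16 of 20, adjusted p = 0.00230) were the others. Without WT ZT16 replicate 1 PPAR targets had a median of -0.04 (adjusted p = 0.184), fatty acid synthesis -0.08 (adjusted p = 0.0909) and cholesterol synthesis -0.15 (adjusted p = 0.000508). By fry 0 lists were called, directional or mixed. Core clock genes did not pass (median -0.08, n = 17, adjusted p = 0.230). Their smallest p was that of Ciart, a repressor of the clock (4.40 ± 2.26 and 2.54 ± 0.179, adjusted p = 0.999), and Arntl differed by -0.18 ± 0.15 (adjusted p = 0.999).

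Under LKO serum, the same night-minus-day question was asked. Snhg6 and Tmem208 were lower under night serum. Snhg6 fell from an FPKM of 82.5 ± 10.6 in LKO ZT4 to 51.5 ± 4.95 in LKO ZT16 (-0.67 ± 0.10, adjusted p = 0.0315), and Tmem208, an ER membrane protein, from 92.7 ± 4.11 to 68.0 ± 2.75 (-0.44 ± 0.07, adjusted p = 0.0315). In both genes all 4 LKO ZT16 libraries lay below all 4 LKO ZT4 libraries, and the groups were apart in 590 genes (4.999% against 2.86% by chance). Rps27rt had 4658 ± 1029 and 2807 ± 131, and the growth factor Fgf2 2.07 ± 0.419 and 3.93 ± 0.716.

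Those 2 genes, both lower, were the ones that passed, and 1403 genes had an unadjusted p under 0.05. Not passing on the lower side were Rps27rt (-0.70 ± 0.12) and Tmem150a, a membrane protein (-0.33 ± 0.06), with an adjusted p of 0.0675, and Rps21 (-0.80 ± 0.15, adjusted p = 0.0869). Not passing on the higher side were the apoptosis inhibitor Xiap (0.35 ± 0.07) and the volume-regulated anion channel subunit Lrrc8b (0.36 ± 0.07), both at an adjusted p of 0.0869. Further down were Fgf2 (0.68 ± 0.14, adjusted p = 0.160), the forkhead factor Foxn3 (0.49 ± 0.11) and the cell cycle repressor Rbl1 (0.31 ± 0.07), both at 0.191. Arntl differed by -0.19 ± 0.15 (adjusted p = 0.643). Over the alternatives the change of Snhg6 ran from -0.74 to -0.57 (adjusted p from 0.00330 to 0.260) and that of Tmem208 from -0.47 to -0.34 (0.0148 to 0.218). With library weights 13 genes passed, 2 higher and 11 lower, and 1 with the length trend removed, neither Snhg6 nor Tmem208. None passed without the filter on low values, with the same summed FPKM, with the block by titles or in a fit of only the 2 groups. The count was 59 without LKO ZT4 replicate 1, 5 without LKO ZT4 replicate 3, and 0 without LKO ZT4 replicate 2 or 4 or any 1 of the 4 LKO ZT16 libraries.

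Of the 36 lists, 11 differed under LKO serum, 2 higher and 9 lower, and 0 with an estimated correlation. Cytosolic ribosomal proteins were lower (median -0.18, 74 of 77 lower, 30 passing over the list alone, adjusted p = 9.12e-26, adjusted p = 0.603 with an estimated correlation), including Rpl39 (-0.52 ± 0.11) and Rpl38 (-0.80 ± 0.20). Oxidative phosphorylation genes were lower (median -0.14, 71 of 78, 14 over the list alone, adjusted p = 1.81e-13 and 0.607 with an estimated correlation), including Ndufa7 of complex I (-0.31 ± 0.08), Cox7a2 (-0.33 ± 0.09) and Cox6c (-0.36 ± 0.10). All 31 proteasome genes were lower (median -0.13, 10 over the list alone, adjusted p = 2.85e-12 and 0.603), with Psmd8 at -0.20 ± 0.06 and Psmb4 at -0.20 ± 0.06. NRF2 antioxidant genes were lower (median -0.12, 23 of 32, 1 over the list alone, adjusted p = 0.00133 and 0.701), led by the metallothioneins Mt1 (FPKM 554 ± 147 in LKO ZT4 and 341 ± 74.8 in LKO ZT16) and Mt2 (569.8 ± 159 and 362 ± 113). In LKO ZT4 the ribosomal list score had an SD of 0.16 and the oxidative phosphorylation scores were 7.56, 7.88, 7.52 and 7.91 in replicates 1 to 4. These scores followed the order of the short-minus-long values of that group, and without replicate 4 the oxidative phosphorylation median was -0.08 (adjusted p = 3.58e-06). It was -0.09 with the length trend removed, -0.08 with length and GC trends removed and -0.03 among transcripts of at least 1000 nt (adjusted p = 0.00646), and the proteasome median was -0.08 with the length trend removed. The NRF2 median was -0.03 without LKO ZT4 replicate 1 (adjusted p = 0.0809) and among transcripts of at least 1000 nt (adjusted p = 0.102), -0.05 with library weights and -0.08 with length and GC trends removed.

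Mitochondrial ribosomal proteins were called lower (median -0.08, 64 of 77, adjusted p = 1.33e-06 and 0.701 with an estimated correlation, -0.14 without LKO ZT4 replicate 3 and -0.05 with the length trend removed, with length and GC trends removed or among transcripts of at least 1000 nt), and so were autophagy and lysosome genes (-0.06, 30 of 39, adjusted p = 0.00144 and 0.607). ER folding genes (-0.25, 23 of 23, adjusted p = 0.00124 and 0.755) and ATF4 targets (-0.13, 33 of 36, adjusted p = 0.000549 and 0.755) were lower, but without LKO ZT4 replicate 1 their medians were 0.015 (adjusted p = 0.863) and -0.02 (adjusted p = 0.625). The ER median was -0.08 without LKO ZT16 replicate 4 (adjusted p = 0.349), -0.42 without LKO ZT4 replicate 4 and -0.41 without LKO ZT16 replicate 2, and the ATF4 median -0.20 without LKO ZT4 replicate 4. SRF and actin genes (-0.10, 24 of 36, adjusted p = 0.0121 and 0.755) had -0.07 without LKO ZT4 replicate 4 (adjusted p = 0.246) or LKO ZT16 replicate 1 (adjusted p = 0.161), -0.06 with library weights (adjusted p = 0.323), -0.07 with length and GC trends removed (adjusted p = 0.0748) and -0.05 among transcripts of at least 1000 nt. With the same summed FPKM per library mitochondrial ribosomal proteins (0.026, adjusted p = 0.000754) and SRF and actin genes (0.0020, adjusted p = 0.00274) stayed called, and autophagy and lysosome genes (0.038, adjusted p = 0.0567) were lost. Thyroid hormone targets (0.16, 8 of 10, adjusted p = 0.0207 and 0.607) and insulin and IGF signalling genes (0.09, 15 of 19, adjusted p = 0.0260 and 0.603) were called higher. The thyroid call was lost without LKO ZT4 replicate 1 or 4 or LKO ZT16 replicate 4 (adjusted p = 0.0809, 0.0865 and 0.0540), and the insulin call without LKO ZT4 replicate 1 or 3 or LKO ZT16 replicate 1 (adjusted p = 0.129, 0.113 and 0.0660). Of 12 other settings each was lost under 4 (adjusted p up to 0.222 and 0.201). Among insulin and IGF signalling genes were Pik3r1, the regulatory subunit of PI 3-kinase (7.07 ± 0.344 and 8.57 ± 0.689), and Igfbp5 (113 ± 40.8 and 163 ± 41.4). Core clock genes did not pass (median 0.10, adjusted p = 0.192). By fry and by the exact permutation of list scores 0 lists were called.

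At ZT4, the question was what deletion of Bmal1 in the donors' liver did to the effect of day serum. Snhg6 was higher under LKO serum. It rose from 48.3 ± 5.09 in WT ZT4 to 82.5 ± 10.6 in LKO ZT4 (0.76 ± 0.10, adjusted p = 0.0111, and over the alternatives 0.68 to 0.83 with adjusted p from 0.00132 to 0.107). The oligosaccharyltransferase subunit Krtcap2 had 321 ± 21.7 and 433 ± 21.1, and the coatomer subunit Cope 75.1 ± 6.42 and 99.3 ± 4.61. Isg15, a ubiquitin-like protein induced by interferon, had 1.81 ± 0.380 and 3.65 ± 0.785. The ER chaperone cofactor Sdf2l1 had 35.2 ± 5.85 and 110.1 ± 71.8.

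Snhg6 was the 1 gene that passed, with 1213 genes at an unadjusted p under 0.05 and 466 genes (3.95% against 2.86% by chance) without overlap between groups. Higher and not passing were Krtcap2 (0.43 ± 0.07, adjusted p = 0.0547), Cdk5rap3, a factor of the ER ufmylation pathway (0.38 ± 0.06, adjusted p = 0.0650), Cope (0.40 ± 0.07) and Rps27rt (0.67 ± 0.12), both at an adjusted p of 0.0754. Lower and not passing were Fgf2 (-0.68 ± 0.14, adjusted p = 0.157) and the Ras GTPase activator Rasa3 (-0.22 ± 0.05, adjusted p = 0.203). So were the microtubule protein Eml1 (-0.22 ± 0.05, adjusted p = 0.216), the transcription factor Ebf3 (-0.31 ± 0.08) and the ubiquitin-conjugating enzyme Ube2a (-0.21 ± 0.05), both at 0.234. With library weights 3 genes passed, with the block by column names 3 and with at least 2 FPKM 2, all higher. None passed without the filter on low values, with the same summed FPKM or with the length trend removed. The count was 16 without LKO ZT4 replicate 1, 2 without WT ZT4 replicate 2, and 0 without WT ZT4 replicate 1, 3 or 4 or LKO ZT4 replicate 3 or 4.

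Of the 36 lists, 20 differed at ZT4, 17 higher and 3 lower, 0 with an estimated correlation, and 13 did without LKO ZT4 replicate 1. All 23 ER folding genes were higher (median 0.72, 22 over the list alone, adjusted p = 5.94e-19, adjusted p = 0.422 with an estimated correlation). Sdf2l1 was higher by 1.41 ± 0.40, the BiP cofactors Dnajb9 by 0.84 ± 0.24 and Dnajb11 by 0.61 ± 0.18, and the secreted factor Manf by 0.93 ± 0.28. Their mean log2(FPKM+1) was 6.42 ± 0.10 in WT ZT4 and 7.91, 7.14, 7.01 and 6.49 in LKO ZT4 replicates 1 to 4, replicate 1 being the library set apart on the leading component. Without it the ER median was 0.46 (adjusted p = 2.42e-11). The exact permutation p of that score was 0.0571 (adjusted 0.294). Interferon-stimulated genes rose (median 0.17, 14 of 18, 3 over the list alone, adjusted p = 3.41e-05 and 0.0512 with an estimated correlation), and fry called this list (adjusted p = 0.00694). Without the filter on low values, over 47 genes, the median was 0.05 (adjusted p = 4.79e-05). Isg15 (0.72 ± 0.14), the MHC class I gene H2-D1 (0.48 ± 0.11), Irf9, part of the interferon transcription complex (0.37 ± 0.09), and the RNA sensor Ddx58 (0.32 ± 0.12) had the smallest p. The interferon score was 2.66 ± 0.07 in WT ZT4 and 2.83 ± 0.02 in LKO ZT4 (exact permutation p = 0.0286, the smallest possible, adjusted 0.294).

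Cytosolic ribosomal proteins (median 0.09, 70 of 77 higher, 1 over the list alone, adjusted p = 1.55e-10 and 0.549 with an estimated correlation) and oxidative phosphorylation genes (0.12, 66 of 78, adjusted p = 2.62e-09 and 0.549) were higher at ZT4, in the group whose short-minus-long values spread from -0.13 to 0.23. The ribosomal median was 0.15 without LKO ZT4 replicate 3 and 0.05 without replicate 4, and the oxidative phosphorylation median 0.19 without replicate 3, 0.06 without replicate 2 and 0.07 without replicate 4. Among transcripts of at least 1000 nt the oxidative phosphorylation list was lost (0.03, adjusted p = 0.0706), and with length and GC trends removed it had 0.08. The ribosomal median was 0.05 with the length trend removed or with length and GC trends removed. The proteasome rose (0.11, 29 of 31, 1 over the list alone, adjusted p = 1.10e-09 and 0.422), with Psmb4 at 0.25 ± 0.06. Cholesterol synthesis genes were higher (0.25, 25 of 25, adjusted p = 1.26e-06 and 0.549), among them Tm7sf2 (7.76 ± 1.12 and 11.3 ± 2.41) and Dhcr7 (31.2 ± 1.57 and 37.4 ± 2.68), but without LKO ZT4 replicate 1 their median was 0.10 (adjusted p = 0.0530), and with library weights 0.15. Hypoxia targets were higher (0.22, 19 of 20, 1 over the list alone, adjusted p = 3.27e-05 and 0.549), 0.05 without that library (adjusted p = 0.0505) and 0.13 among transcripts of at least 1000 nt, led by the collagen prolyl hydroxylases P4ha2 (17.6 ± 1.05 and 28.8 ± 9.73) and P4ha1 (23.1 ± 2.38 and 37.9 ± 16.4). Autophagy and lysosome genes rose (0.07, 31 of 39, 4 over the list alone, adjusted p = 1.81e-05 and 0.422), with the lysosomal enzymes Hexa (0.20 ± 0.05) and Ctsd (0.24 ± 0.07). NRF2 targets (0.12, 27 of 32, adjusted p = 3.41e-05 and 0.549, and 0.06 among transcripts of at least 1000 nt) rose too. ATF4 targets (0.09, 27 of 36, adjusted p = 0.0318 and 0.787) had -0.042 without LKO ZT4 replicate 1 (adjusted p = 0.619) and were lost without WT ZT4 replicate 1, 3 or 4 (0.03, 0.00 and 0.07, adjusted p = 0.476, 0.679 and 0.188), and had 0.22 without WT ZT4 replicate 2 and 0.15 without LKO ZT4 replicate 4. Among transcripts of at least 1000 nt they had 0.06 (adjusted p = 0.0761). Ddit3, the stress factor CHOP, had 23.9 ± 11.3 and 55.6 ± 41.6.

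Other lists called higher at ZT4 had smaller medians, with adjusted p from 0.000298 to 0.0438, and from 0.422 to 0.787 with an estimated correlation. Glycolysis (0.13, and 0.06 without LKO ZT4 replicate 1 or 0.20 without replicate 4) and fatty acid oxidation (0.05) were kept in all 8 runs that left out 1 library. Fatty acid synthesis (0.09) turned to -0.023 without LKO ZT4 replicate 1 (adjusted p = 0.723), was lost without WT ZT4 replicate 1 or 4 (adjusted p = 0.0660 and 0.0536), and had 0.15 without LKO ZT4 replicate 4. LXR targets (0.10) were lost without WT ZT4 replicate 1, 2 or 3 or LKO ZT4 replicate 1, 2 or 4 (adjusted p = 0.0660, 0.192, 0.0517, 0.0735, 0.128 and 0.0661). Heat shock genes (0.08) were lost without WT ZT4 replicate 2 or 4 or LKO ZT4 replicate 1 or 4 (0.04, 0.08, 0.03 and 0.08, adjusted p = 0.107, 0.139, 0.375 and 0.0845). PPAR targets (0.07) were lost without WT ZT4 replicate 1 or 3 or LKO ZT4 replicate 2 or 4 (0.04, 0.04, 0.04 and 0.08, adjusted p = 0.137, 0.137, 0.112 and 0.0637), and had 0.11 without LKO ZT4 replicate 3. Myotube genes (0.05) were lost without WT ZT4 replicate 2 or 3 or LKO ZT4 replicate 2 or 4 (0.04, 0.03, 0.00 and 0.03, adjusted p = 0.130, 0.138, 0.849 and 0.101), and had 0.11, 0.11 and 0.10 without WT ZT4 replicate 1, LKO ZT4 replicate 1 and LKO ZT4 replicate 3.

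Called lower at ZT4 were cell cycle (-0.06), ribosome biogenesis (-0.08) and NF-kappaB target genes (-0.11), with adjusted p of 0.00538, 0.0176 and 0.0206 (0.549, 0.787 and 0.613 with an estimated correlation). Cell cycle genes were lost without WT ZT4 replicate 3 or LKO ZT4 replicate 1 (-0.02 and -0.05, adjusted p = 0.321 and 0.0757). Ribosome biogenesis was lost without WT ZT4 replicate 2 or 3 or LKO ZT4 replicate 3 or 4 (-0.02, -0.04, -0.02 and -0.06, adjusted p = 0.702, 0.399, 0.3398 and 0.0661), and had -0.14 without WT ZT4 replicate 4 or LKO ZT4 replicate 1. NF-kappaB targets were lost without WT ZT4 replicate 2 or LKO ZT4 replicate 1 or 2 (-0.06, -0.04 and -0.07, adjusted p = 0.114, 0.693 and 0.159), and had -0.17 and -0.24 without LKO ZT4 replicates 3 and 4. Their calls, and those of LXR targets, were lost among transcripts of at least 1000 nt as well (adjusted p = 0.0622, 0.0779, 0.0909 and 0.0706). Of 12 settings other than a left-out library heat shock genes were lost under 4 (adjusted p up to 0.129), PPAR targets under 3 (up to 0.128), NF-kappaB targets under 3 (up to 0.0909) and LXR targets under 2 (up to 0.0779).

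With the same summed FPKM per library fatty acid oxidation (-0.020, adjusted p = 0.0215), myotube genes (-0.022, adjusted p = 0.00604) and PPAR targets (-0.0030, adjusted p = 0.0132) stayed called at ZT4. Medians moved with library weights to 0.09 for fatty acid oxidation, 0.06 for fatty acid synthesis, 0.14 for myotube genes, -0.04 for cell cycle and -0.21 for NF-kappaB targets. Without the filter on low values they were 0.05 for fatty acid synthesis and 0.03 for LXR targets, and with length and GC trends removed 0.04 for fatty acid oxidation and 0.03 for myotube genes. At ZT4 fry called 1 list directional and 1 mixed, and the exact permutation 0.

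At ZT16, the question was what the deletion did to the effect of night serum. Under LKO serum 6 genes were lower than under WT serum and 0 higher. Ass1, the argininosuccinate synthase of arginine production, fell from 31.8 ± 1.69 in WT ZT16 to 12.4 ± 4.95 in LKO ZT16 (-1.36 ± 0.22, adjusted p = 0.0387). Slirp, which binds mitochondrial mRNA, fell from 288 ± 16.7 to 173 ± 21.6 (-0.74 ± 0.13, adjusted p = 0.0425). Rps27rt fell from 4964 ± 251 to 2807 ± 131 (-0.82 ± 0.12) and Rpl39 from 2331 ± 164 to 1411 ± 46.8 (-0.72 ± 0.11), both with an adjusted p of 0.0296. Rps21 fell from 3199.7 ± 219.7 to 1735 ± 153 (-0.88 ± 0.15, adjusted p = 0.0387). In each of these genes the 4 libraries of WT ZT16 lay above all 4 of LKO ZT16. Groups without overlap, in either direction, were found in 1401 genes (11.9% against 2.86% by chance).

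The sixth gene was a predicted one, and 1506 genes had an unadjusted p under 0.05. With every library scaled to the same summed FPKM 9 genes passed, 3 higher and 6 lower, with library weights 255 (95 higher and 160 lower) and in a fit of only the 2 groups 132 (22 and 110), the 6 among them each time. With median-ratio scaling 2 passed, with the block by column names 3, and 0 without the filter on low values, with the block by titles or among transcripts of at least 1000 nt. Of the named calls only Ass1 reaches that length. Higher and not passing were Tecrl (0.56 ± 0.10, adjusted p = 0.0763), Akr1b7 (0.63 ± 0.12, adjusted p = 0.09998) and Chpt1 (0.31 ± 0.06, adjusted p = 0.114). So were the fatty acid desaturase Scd1 (0.62 ± 0.13, adjusted p = 0.141) and the receptor Mrgprf (0.60 ± 0.13, adjusted p = 0.161). Rpl38 (-1.002 ± 0.20) was lower with an adjusted p of 0.113. Of the 6 calls 0 were kept in 7 of the 8 runs that left out 1 library, and 1, Ass1, without LKO ZT16 replicate 4 (adjusted p = 0.0364). Without WT ZT16 replicate 2 another gene passed, higher, and in the remaining runs 0 did. The changes themselves stayed about as large over the alternatives, -1.54 to -1.19 for Ass1 (adjusted p from 0.00491 to 0.207), -0.82 to -0.63 for Slirp (0.00246 to 0.222), -0.85 to -0.71 for Rps27rt (0.000160 to 0.184), -0.75 to -0.61 for Rpl39 and -0.92 to -0.77 for Rps21.

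Of the 36 lists, 20 differed at ZT16, 11 higher and 9 lower, and 0 were called with an estimated correlation (smallest adjusted p = 0.222). ER folding genes rose (median 0.74, 23 of 23, 19 over the list alone, adjusted p = 4.74e-15 and 0.222 with an estimated correlation). The chaperone Hspa5 (BiP) had 379 ± 10.96 in WT ZT16 and 949.6 ± 473 in LKO ZT16, Sdf2l1 24.1 ± 2.56 and 73.3 ± 40.7. The ER-associated degradation genes followed, Herpud1 with 72.8 ± 7.03 and 137 ± 48.6 and Edem1 with 12.7 ± 0.861 and 23.5 ± 7.45. Cholesterol synthesis rose (0.41, 25 of 25, 1 over the list alone, adjusted p = 1.77e-12 and 0.246), with Fdps (0.66 ± 0.22), Hmgcs1 (0.57 ± 0.20) and Dhcr7 (0.30 ± 0.08). Fatty acid synthesis rose (0.19, 19 of 20, 6 over the list alone, adjusted p = 4.13e-07 and 0.222), with Scd1 (57.3 ± 6.13 and 88.8 ± 10.7), Scd2 (131 ± 11.03 and 202 ± 35.9) and the elongase Elovl6 (14.1 ± 1.78 and 20.02 ± 2.98). PPAR targets rose (0.18, 22 of 24, 3 over the list alone, adjusted p = 2.96e-06 and 0.222), with Plin2 (445 ± 153 and 691 ± 117), Pdk4 (34.7 ± 11.8 and 50.2 ± 7.19), the acyl-CoA synthetase Acsl1 (4.86 ± 0.631 and 6.88 ± 0.519) and the uncoupling protein Ucp3 (0.965 ± 0.282 and 1.67 ± 0.134).

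Cytosolic ribosomal proteins fell at ZT16 (median -0.23, 75 of 77 lower, 2 passing over all genes and 54 over the list alone, adjusted p = 2.88e-38 and 0.222 with an estimated correlation). Oxidative phosphorylation genes fell (-0.17, 72 of 78, 16 over the list alone, adjusted p = 7.59e-19 and 0.222), with Ndufa3 (-0.68 ± 0.15) and Cox7a2 (-0.39 ± 0.09), and had -0.08 among transcripts of at least 1000 nt (adjusted p = 0.000192). The short-minus-long value was -0.05 ± 0.04 in LKO ZT16 against 0.07 ± 0.05 in WT ZT16. Mitochondrial ribosomal proteins (-0.09, 69 of 77, adjusted p = 4.25e-09 and 0.246) were lower, and stayed called with the same summed FPKM per library (0.016, adjusted p = 5.41e-06). SRF and actin genes (-0.16, 34 of 36, adjusted p = 1.80e-06 and 0.222) and TGF-beta targets (-0.11, 20 of 26, 2 over the list alone, adjusted p = 0.000447 and 0.246) fell. Among them were Ctgf (95.3 ± 40.6 and 49.7 ± 16.2), Id3 (91.8 ± 21.2 and 54.6 ± 10.3), Timp1 (1819 ± 123 and 1296 ± 90.3) and the smooth muscle actin-binding gene Tagln (566 ± 74.2 and 432 ± 39.1). The SRF median was -0.10 without LKO ZT16 replicate 1 and -0.08 among transcripts of at least 1000 nt, and the TGF-beta median -0.05 without WT ZT16 replicate 2 and -0.07 without replicate 3, all still called.

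LXR targets (0.15, 7 of 10, 2 over the list alone, adjusted p = 0.0207 and 0.222 with an estimated correlation, 0.0532 without LKO ZT16 replicate 2 and 0.0861 with at least 2 FPKM) were higher at ZT16, with the phospholipid acyltransferase Lpcat3 at 27.4 ± 2.50 and 34.4 ± 2.19. Interferon-stimulated genes (0.14, 12 of 18, adjusted p = 0.0127 and 0.222) were higher, with Isg15 at 2.16 ± 0.389 and 3.35 ± 0.610. This call was lost without the filter on low values (47 genes, median 0.02, adjusted p = 0.0918) and with the same summed FPKM per library (adjusted p = 0.0601). Core clock genes (0.14, 12 of 17, adjusted p = 0.0209 and 0.222) were higher, with the repressors Cry1 at 7.47 ± 0.461 and 9.72 ± 2.22 and Cry2 at 4.41 ± 0.346 and 5.21 ± 0.210. The clock call was lost without WT ZT16 replicate 4 (adjusted p = 0.0656) or LKO ZT16 replicate 4 (adjusted p = 0.0642), with the length trend removed (0.07, adjusted p = 0.0576), with at least 2 FPKM (adjusted p = 0.0861) and with the same summed FPKM per library (adjusted p = 0.0905). ATF4 targets (0.13) and fatty acid oxidation (0.09) rose (adjusted p = 0.662 and 0.246 with an estimated correlation). Thyroid hormone targets (0.09) and insulin and IGF signalling (0.08) were called higher (adjusted p = 0.261 and 0.222 with an estimated correlation). The thyroid call was lost without WT ZT16 replicate 1 or 4 or LKO ZT16 replicate 4 (adjusted p = 0.113, 0.0656 and 0.106), and the insulin call without WT ZT16 replicate 3 or 4 or LKO ZT16 replicate 1 or 3 (adjusted p = 0.122, 0.0656, 0.0899 and 0.0735). Of 12 other settings they were lost under 7 and 5 (adjusted p up to 0.156 and 0.107). STAT3 targets (-0.12) fell and NF-kappaB targets (-0.13) were called lower (adjusted p = 0.222 and 0.597 with an estimated correlation). The NF-kappaB call was lost without WT ZT16 replicate 1 or LKO ZT16 replicate 2 or 3 (adjusted p = 0.180, 0.0804 and 0.187), and its median was -0.21 without WT ZT16 replicate 3, -0.24 without LKO ZT16 replicate 4 and -0.07 without the filter on low values. The STAT3 median was -0.08 without that filter or among transcripts of at least 1000 nt. Ribosome biogenesis (-0.07) and the proteasome (-0.06) were called lower (adjusted p = 0.597 and 0.575 with an estimated correlation). With the same summed FPKM per library ribosome biogenesis stayed called (0.034, adjusted p = 0.000755) and the proteasome was lost (0.049, adjusted p = 0.824), as it was with the length trend removed (-0.04, adjusted p = 0.0547). The ribosome biogenesis median was -0.12 without WT ZT16 replicate 2. The exact permutation p was 0.0286, the smallest possible with 4 libraries per group, for 10 lists, which is 0.103 after adjustment. In this comparison fry called 0 directional and 3 mixed.

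Scores of some lists are shown per library.

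**Figure D1:**
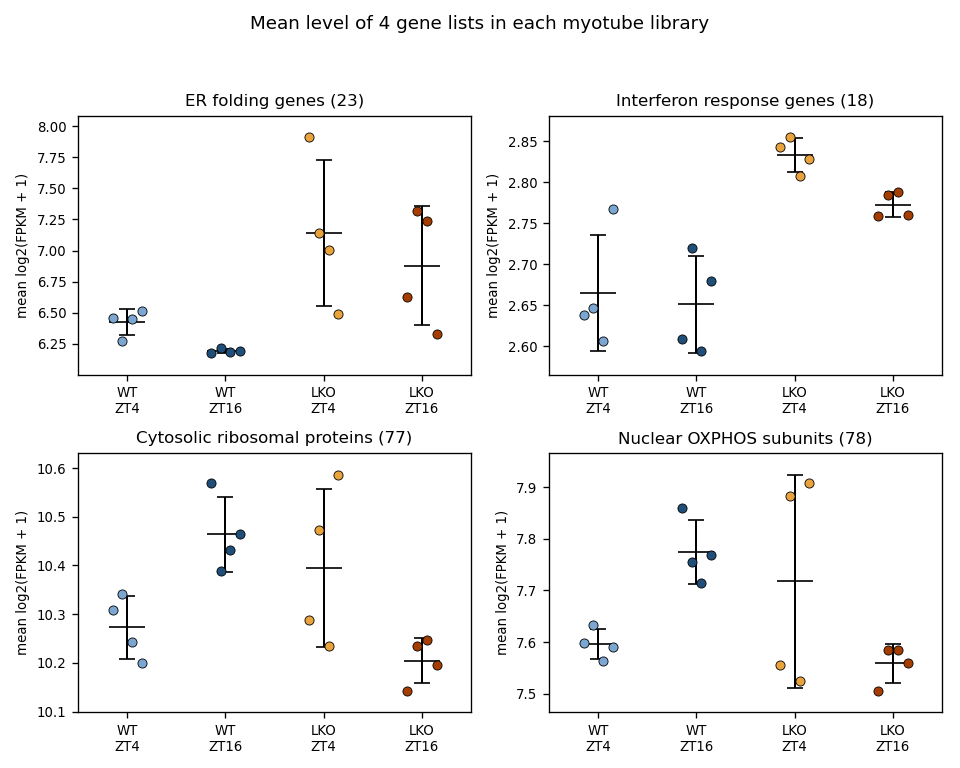
Mean log2(FPKM+1) per library of 23 ER folding genes, 18 interferon-stimulated genes, 77 cytosolic ribosomal protein genes and 78 nuclear oxidative phosphorylation genes, with group mean ± SD (n = 4 libraries) and axes that do not start at 0. ER folding scores were 6.42 ± 0.10 in WT ZT4, 6.19 ± 0.02 in WT ZT16, 7.14 ± 0.59 in LKO ZT4 and 6.88 ± 0.48 in LKO ZT16.

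The interaction asked whether the night-minus-day change differed between LKO and WT serum. For Snhg6, Rps27rt and Rps21 it was opposite: values were higher at night under WT serum and lower at night under LKO serum. Snhg6 had 48.3 ± 5.09, 73.9 ± 7.44, 82.5 ± 10.6 and 51.5 ± 4.95 in WT ZT4, WT ZT16, LKO ZT4 and LKO ZT16 (interaction -1.27 ± 0.14, adjusted p = 0.000591). In the same order Rps27rt had 2875 ± 98.2, 4964 ± 251, 4658 ± 1029 and 2807 ± 131 (-1.49 ± 0.17, adjusted p = 0.000591) and Rps21 1863 ± 223, 3199.7 ± 219.7, 3096 ± 823 and 1735 ± 153 (-1.58 ± 0.21, adjusted p = 0.00346). Slirp had 199.6 ± 17.5, 288 ± 16.7, 267 ± 61.1 and 173 ± 21.6 (-1.13 ± 0.18, adjusted p = 0.0144). Chpt1 changed the other way, with 23.1 ± 2.33, 19.3 ± 0.632, 19.95 ± 0.527 and 24.2 ± 0.971 (0.51 ± 0.09, adjusted p = 0.0268).

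**Figure D2:**
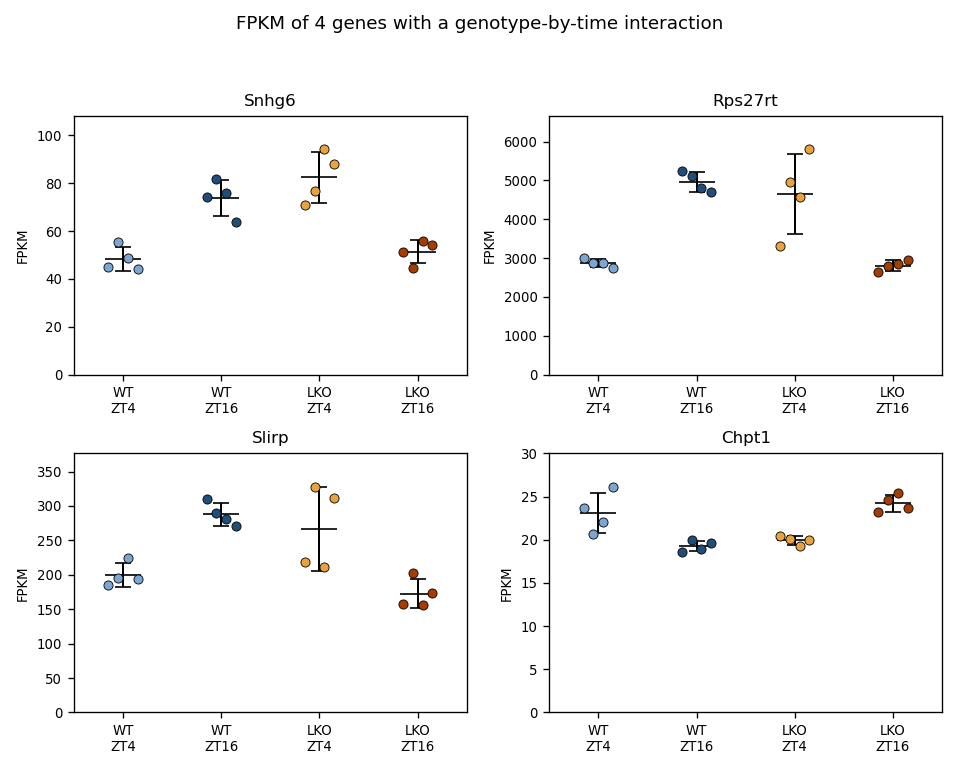
FPKM of Snhg6, Rps27rt, Slirp and Chpt1 in each library, with group mean ± SD (n = 4 libraries). Snhg6 was 48.3 ± 5.09 in WT ZT4, 73.9 ± 7.44 in WT ZT16, 82.5 ± 10.6 in LKO ZT4 and 51.5 ± 4.95 in LKO ZT16.

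In total 11 genes had an interaction, 1 positive (Chpt1) and 10 negative, with 1210 genes at an unadjusted p under 0.05. The others were Rpl34-ps1 (-1.12 ± 0.17) and Rpl39 (-1.04 ± 0.15), both at an adjusted p of 0.00982, and the predicted gene Gm12191 (-0.61 ± 0.09, adjusted p = 0.0125). Rpl38 (-1.64 ± 0.28) and Tmem208 (-0.56 ± 0.10), both at an adjusted p of 0.0256, and Cox7a2 (-0.69 ± 0.12, adjusted p = 0.0342) completed them. With every library scaled to the same summed FPKM 17 genes passed, 7 positive and 10 negative, with library weights 127 (7 and 120), with at least 2 FPKM 23 (3 and 20), with the block by titles 6 and without the filter on low values 3, all negative in the last pair. The count was 109 without LKO ZT4 replicate 1, 39 without LKO ZT4 replicate 3 and 6 without LKO ZT16 replicate 1. Snhg6, Rps27rt, Rps21, Rpl34-ps1, Rpl39 and Gm12191 passed with any 1 of the 16 libraries left out. Slirp passed without any but LKO ZT16 replicate 1 (adjusted p = 0.0528, 0.000524 to 0.0575 over the alternatives), and Tmem208, Chpt1, Rpl38 and Cox7a2 in 10, 8, 8 and 4 of the 16 runs. The 10 negative genes had a median annotated transcript length of 476.5 nt against 2106.75 nt for all tested genes.

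Of the 36 lists, 7 were called, 0 with an estimated correlation, all negative (0 and 7, against 1 and 8 with the same summed FPKM). Cytosolic ribosomal proteins had a median of -0.32 (75 of 77 negative, 3 passing over all genes and 51 over the list alone, adjusted p = 8.35e-44 and 0.530 with an estimated correlation). Oxidative phosphorylation genes had -0.28 (71 of 78, 31 over the list alone, adjusted p = 2.59e-26 and 0.540), with Ndufa3 (-1.15 ± 0.22, adjusted p = 0.0545) and Cox6c (-0.67 ± 0.14, adjusted p = 0.0758) next after Cox7a2, and had -0.17 with length and GC trends removed and -0.08 among transcripts of at least 1000 nt (adjusted p = 4.23e-05). Short-minus-long values had the same pattern over the groups: -0.05 ± 0.02 in WT ZT4, 0.07 ± 0.05 in WT ZT16, 0.04 ± 0.17 in LKO ZT4 and -0.05 ± 0.04 in LKO ZT16. The proteasome had -0.17 (31 of 31, 8 over the list alone, adjusted p = 4.81e-11 and 0.540), with Psmb4 (-0.31 ± 0.08) and Psma2 (-0.30 ± 0.08). Mitochondrial ribosomal proteins had -0.13 (62 of 77, 1 over the list alone, adjusted p = 4.22e-08 and 0.720), with Mrpl33 (366 ± 17.2, 482 ± 28.4, 502 ± 103 and 368 ± 45.3). NRF2 antioxidant genes had -0.11 (21 of 32, 3 over the list alone, adjusted p = 0.0117 and 0.736), with Mt1 (379 ± 36.8, 498 ± 70.9, 554 ± 147 and 341 ± 74.8) and Mt2 (-1.12 ± 0.30). SRF and actin genes (-0.15, 26 of 36, adjusted p = 0.00378 and 0.720) and autophagy and lysosome genes (-0.07, 32 of 39, adjusted p = 0.0117 and 0.720) were the rest. The interaction of NRF2 genes was 0.0039 without WT ZT16 replicate 4 (adjusted p = 0.293) and -0.07 without LKO ZT4 replicate 1 (adjusted p = 0.120), that of SRF and actin genes -0.09 without LKO ZT4 replicate 4, and autophagy and lysosome genes were lost without WT ZT4 replicate 3 (adjusted p = 0.0503).

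With the same summed FPKM per library the proteasome (0.020, adjusted p = 0.00139), mitochondrial ribosomal proteins (0.058, adjusted p = 0.00109), NRF2 genes (0.073, adjusted p = 0.00627) and SRF and actin genes (0.030, adjusted p = 0.00109) stayed called as lower than other genes, and autophagy and lysosome genes (0.11, adjusted p = 0.343) were lost. With the length trend removed the proteasome had -0.10 and mitochondrial ribosomal proteins -0.07. NRF2 genes were lost with length and GC trends removed (adjusted p = 0.0815) and among transcripts of at least 1000 nt (0.0078, adjusted p = 0.419). With library weights SRF and actin genes (-0.10, adjusted p = 0.102) and autophagy and lysosome genes (adjusted p = 0.0688) were lost. The number of lists was 17 without WT ZT16 replicate 2, 14 without WT ZT4 replicate 3, 12 without LKO ZT4 replicate 2 and 11 without LKO ZT4 replicate 1. ER folding genes (-0.02, adjusted p = 0.770), interferon-stimulated genes (-0.02, adjusted p = 0.348) and core clock genes (0.14, adjusted p = 0.0937) were not called. Among the clock genes Nr1d2 (0.27 ± 0.11, adjusted p = 0.423) had the smallest p, and the interaction of Arntl was -0.01 ± 0.21 (adjusted p = 0.992). Here fry called 0 lists as directional and 3 as mixed.

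**Figure D3:**
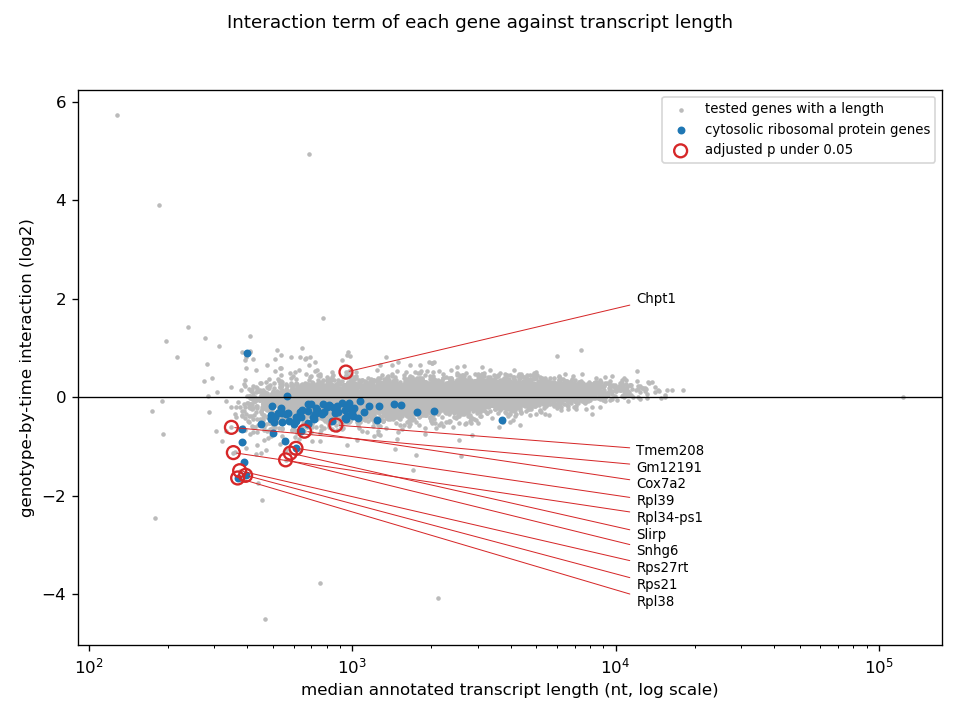
Interaction of each tested gene (difference of log2(FPKM+1) changes) by median annotated transcript length, with cytosolic ribosomal protein genes in blue and genes with an adjusted p under 0.05 ringed in red. The called negative genes had a median length of 476.5 nt against 2106.75 nt for all tested genes.

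Across all 11802 genes, night-minus-day changes under LKO serum were weakly opposed to those under WT serum (r = -0.20, rho = -0.16), with an exact permutation p of 0.200 over 70 assignments of libraries, under which r ran from -0.29 to 0.29. LKO-minus-WT changes at ZT16 and ZT4 were close to unrelated (r = 0.08, exact permutation p = 0.543, permuted r from -0.28 to 0.28). Genes are not independent replicates, so only these permutations over libraries were used as a test.

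Averaged over ZT4 and ZT16, a comparison added later, 0 genes passed between LKO and WT serum, and 22 lists did, among them interferon, ER folding and lipid genes with higher values under LKO serum. Of the 22 only the interferon list was called with an estimated correlation. ER folding genes were higher by a median of 0.72, with Sdf2l1 (1.39 ± 0.28), Hspa5 (1.18 ± 0.26), Hsp90b1, the ER chaperone GRP94 (0.90 ± 0.20), and Dnajb9 (0.79 ± 0.17) all at an adjusted p of 0.121. Interferon-stimulated genes were higher by 0.16, with Isg15 (0.59 ± 0.10, adjusted p = 0.108), Irf9 (0.32 ± 0.07, adjusted p = 0.121) and Ddx58 (0.31 ± 0.08, adjusted p = 0.156). Scd1 (0.45 ± 0.09, adjusted p = 0.121), Plin2 (0.56 ± 0.14, adjusted p = 0.136), Acsl1 (0.30 ± 0.07, adjusted p = 0.136) and Lpcat3 (0.25 ± 0.07, adjusted p = 0.164) were higher in the lipid lists.

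In the averaged genotype comparison 0 genes passed, with 1396 genes at an unadjusted p under 0.05, and of the 22 lists 13 were higher and 9 lower. With library weights 103 genes passed, 88 higher and 15 lower. Leaving out LKO ZT4 replicate 4 gave 174 genes, WT ZT16 replicate 4 gave 3 and WT ZT16 replicate 2 gave 1. In 5 lists the exact permutation of list scores also passed. They were interferon (adjusted p = 7.68e-06, 0.0281 with an estimated correlation, exact permutation p = 0.000408, adjusted 0.0147, 16 of 18 genes higher and 7 passing over the list alone) and ER folding (adjusted p = 4.62e-28 and 0.198, exact permutation p = 0.000816, adjusted 0.0147, 23 of 23 over the list alone). LXR targets (0.13, 8 of 10 higher, adjusted p = 0.00197 and 0.1495, exact permutation p = 0.00122, adjusted 0.0147) and PPAR targets (0.12, 22 of 24, 3 over the list alone, adjusted p = 1.36e-06 and 0.198, exact permutation p = 0.00163, adjusted 0.0147) were others. The last was fatty acid oxidation (0.06, 26 of 28, adjusted p = 1.72e-05 and 0.198, exact permutation p = 0.00245, adjusted 0.0176). Cholesterol synthesis (0.34, 18 over the list alone, adjusted p = 2.64e-16 and 0.272, exact permutation p = 0.0208, adjusted 0.107) and fatty acid synthesis (0.13, 18 of 20, adjusted p = 2.72e-07 and 0.198, exact permutation p = 0.0114, adjusted 0.0686) passed by camera and not by the exact permutation. Each of these 7 lists was called in all 16 runs that left out 1 library. Without the filter on low values the interferon median was 0.03 (47 genes, adjusted p = 8.53e-05) and the PPAR median 0.06, and among transcripts of at least 1000 nt they were 0.10 and 0.06. With at least 2 FPKM the PPAR median was 0.08.

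The other 15 lists of the averaged genotype comparison were called by camera and not with an estimated correlation (adjusted p from 0.198 to 0.666) or by the exact permutation. Lower under LKO serum in all 16 runs that left out 1 library were NF-kappaB targets (-0.15), STAT3 targets (-0.12), ribosome biogenesis (-0.09), SRF and actin genes (-0.09), TGF-beta targets (-0.08), cytosolic ribosomal proteins (-0.07) and cell cycle genes (-0.05). Higher in all 16 were hypoxia targets (0.18), ATF4 targets (0.11), glycolysis (0.10) and autophagy and lysosome genes (0.05). Without LKO ZT4 replicate 1 hypoxia targets had 0.08, ATF4 targets 0.05, glycolysis 0.06 and cytosolic ribosomal proteins -0.05, and the last had -0.04 without LKO ZT4 replicate 3. ATF4 targets had 0.20 and ribosome biogenesis -0.05 without WT ZT4 replicate 2, cell cycle genes -0.03 without WT ZT4 replicate 3, and hypoxia targets 0.11 and TGF-beta targets -0.05 without WT ZT16 replicate 3. STAT3 targets had -0.06 without the filter on low values. Mitochondrial ribosomal proteins (-0.04) were lost without LKO ZT4 replicate 3 (-0.01, adjusted p = 0.1505) or WT ZT16 replicate 1 (-0.02, adjusted p = 0.0787) and with library weights (adjusted p = 0.145). NRF2 genes (0.06) were lost without WT ZT16 replicate 3 (adjusted p = 0.0533) and with library weights (adjusted p = 0.0865), and had 0.04 without LKO ZT4 replicate 1. Oxidative phosphorylation (-0.03) was lost without WT ZT4 replicate 2, LKO ZT4 replicate 1 or 3, WT ZT16 replicate 1 or LKO ZT16 replicate 1 (adjusted p = 0.0969, 0.895, 0.474, 0.203 and 0.0654), among transcripts of at least 1000 nt (adjusted p = 0.190) and with library weights (0.0097, adjusted p = 0.756), and had -0.05 and -0.06 without LKO ZT4 replicates 2 and 4. Myotube genes (0.03) were kept in 8 of 16 runs. They were lost without WT ZT4 replicate 2 or 3, LKO ZT4 replicate 2 or 4, WT ZT16 replicate 1 or 4 or LKO ZT16 replicate 3 or 4 (adjusted p from 0.0743 to 0.434), with -0.00090 without WT ZT16 replicate 1. In this comparison fry called 3 directional and 7 mixed.

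Averaged over genotypes, ZT16 differed from ZT4 serum in 10 lists, 3 higher and 7 lower, and in no gene (542 at an unadjusted p under 0.05, smallest adjusted p = 0.316, and 1 gene with library weights). ATF4 targets fell (median -0.18, 36 of 36 lower, adjusted p = 9.83e-16), as did cholesterol synthesis (-0.21, adjusted p = 1.77e-08), ER folding genes (-0.21, adjusted p = 3.28e-08) and the proteasome (-0.04). The ATF4 median was -0.12 without WT ZT4 replicate 2, and without LKO ZT4 replicate 1 the cholesterol median was -0.10 and the ER median -0.11. The ER median was -0.13 without LKO ZT16 replicate 4 and -0.32 without LKO ZT4 replicate 4, and the proteasome median -0.03 with the length trend removed. The other 6 lists had medians from -0.06 to 0.09 and were each kept in 7 to 11 of 16 runs that left out 1 library. They were PPAR targets (-0.06), NRF2 genes (-0.05) and autophagy and lysosome genes (-0.02), called lower, and NF-kappaB targets (0.09), thyroid hormone targets (0.07) and cell cycle genes (0.04), called higher. None of the 10 lists was called with an estimated correlation (smallest adjusted p = 0.702) or by the exact permutation. Leaving out LKO ZT4 replicate 3 gave 1 gene, and leaving out LKO ZT16 replicate 2 gave 6 lists.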

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

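Of the tests in this part, scaling to the same summed FPKM as a test of the interaction, removal of the length trend or of length and GC trends, the exact permutations of list scores and the comparisons averaged over times were chosen after the result was seen.

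An interaction was called in 11 genes: Chpt1 (0.51), Rpl38 (-1.64), Rps21 (-1.58), Rps27rt (-1.49), Snhg6 (-1.27), Slirp (-1.13), Rpl34-ps1 (-1.12), Rpl39 (-1.04), Cox7a2 (-0.69), Gm12191 (-0.61) and Tmem208 (-0.56). It was called in 7 lists as well, but in 0 with an estimated correlation (smallest adjusted p = 0.530), and 92 of 100 groupings of the libraries gave as many lists. The lists were cytosolic ribosomal proteins (-0.32), oxidative phosphorylation (-0.28), the proteasome (-0.17), SRF and actin genes (-0.15), mitochondrial ribosomal proteins (-0.13), NRF2 antioxidant genes (-0.11) and autophagy and lysosome genes (-0.068). All 11 genes have a median annotated transcript length under 1000 nt, 5 of them under 500 nt, against 2106.75 nt for all tested genes, so a recovery of short transcripts that differed between libraries is a candidate explanation. With the length trend of each library removed 16 genes passed, all 11 among them. The 5 under 500 nt were shifted equally, so a steeper effect among these was not removed. For the other genes this argues against a smooth length effect as the whole cause. Scaling to the same summed FPKM gave 17, with 10 of the 11 (Tmem208 adjusted p = 0.0834, 0.00771 to 0.0834 over the alternatives), which argues against composition as the whole cause. With length and GC trends removed together 11 genes passed, 9 of them among the 11. The calls of Chpt1 (0.50 ± 0.09, adjusted p = 0.0568) and Tmem208 (-0.47 ± 0.09, adjusted p = 0.0731) ended, with changes that moved by no more than their SE. Among cytosolic ribosomal protein genes the median interaction was -0.60 under 500 nt (n = 12), -0.31 from 500 to 1000 nt (n = 51) and -0.29 above (n = 14), and -0.46, -0.23 and -0.24 with the trend removed. Reads shared with retrogenes and pseudogenes, fragment size effects that differ among short transcripts, poly-A selection, and an effect of the serum itself stay open.

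ER folding genes were higher under LKO serum by a median of 0.72 averaged over times, with a wide spread among LKO libraries. A single library could have made this: the smallest median on leaving out 1 library was 0.59, without LKO ZT4 replicate 1, which argues against that library as the whole cause. The exact permutation p was 0.000816, where the smallest possible is 0.000408. With the length trend removed the median stayed 0.72, which argues against transcript length as its cause. Under LKO serum the score was 7.91 and 7.14 in ZT4 replicates 1 and 2 and 7.32 and 7.24 in ZT16 replicates 2 and 3, and 7.01 and 6.49 in ZT4 replicates 3 and 4 and 6.63 and 6.32 in ZT16 replicates 1 and 4, which is also the split of LKO libraries that gave the most genes. The score of NF-kappaB targets ran the other way, 3.95, 4.17, 4.34 and 4.24 against 4.46, 4.75, 4.53 and 4.79. By the numbers of the column names, the libraries with high ER scores were 1 and 3 at both times, and the others 2 and 4. What these numbers stand for is not given in the labels. If they mark a shared source, the LKO libraries are not independent, as the exact permutation takes them to be. Why LKO libraries differ in this score was not resolved further.

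Interferon-stimulated genes were higher under LKO serum by a median of 0.16 averaged over times (exact permutation p = 0.000408, the smallest possible). The smallest median on leaving out 1 library was 0.12, without LKO ZT4 replicate 1, and without the filter on low values it was 0.03 over 47 genes. Blood cells or their RNA carried over with serum might add such transcripts, but of Hba-a1, Hbb-bs, Lyz2 and Ptprc the highest group mean was 0.693 FPKM (Hba-a1 in LKO ZT4), and Ptprc was 0 throughout, which argues against carry-over as the main source. Whether interferon or another serum factor acted on the myotubes was not tested.

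In 25 of 520 groups of 4 values, 1 value lay far from the other 3 by Dixon's test, where 26 are expected by chance (1 in 20). WT ZT4 replicates 1 and 2 held 6 each. Among list scores these were cholesterol synthesis in LKO ZT4 replicate 1 (5.85, the others 5.15 to 5.25), SRF and actin genes in WT ZT4 replicate 1 (6.37, others 6.14 to 6.17) and LKO ZT16 replicate 1 (5.95, others 6.10 to 6.13), TGF-beta targets in WT ZT4 replicate 1 (5.71, others 5.46 to 5.48), undifferentiated myoblast genes in WT ZT4 replicate 4 (4.40, others 4.27) and osteoblast markers in LKO ZT16 replicate 2 (4.46, others 4.62 to 4.65).

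Among FPKM values, WT ZT4 replicate 1 stood apart in Rpl34-ps1 (1414), Lrrc8b (6.09), Eml1 (24.6) and Ctgf (117). WT ZT4 replicate 2 stood apart in Gdf15 (53.8, others 24.8 to 29.6), Chac1 (129.7, others 34.9 to 48.8), Ddit3 (40.8, others 17.3 to 19.6), Plin2 (663), Ciart (7.77, others 3.00 to 3.43) and Bcar3 (15.6), and replicate 3 in Elovl6 (21.0). In WT ZT16, replicate 1 stood apart in Rpl38 (3238, others 2319.8 to 2412) and Ndufa3 (282), and replicate 3 in Gdf15 (17.2) and Psmd8 (130.7). In LKO ZT4, replicate 1 stood apart in Mthfd2 (159) and Tm7sf2 (14.8, others 9.65 to 10.3) and replicate 4 in Timp1 (2181, others 1354 to 1403). In LKO ZT16, replicate 2 stood apart in Ciart (4.04).

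Regroupings with as many calls were counted over all 35 splits of a pair's 8 libraries. For the interaction 100 groupings were used, the real one included in each case. For genes 1 of 35 splits gave as many calls between genotypes at ZT16 (6, highest other 1). For the interaction 1 of 100 did (11, highest other 2). Chance stays open for genes in WT serum over time (35 of 35, 0 against a highest other of 1), LKO serum over time (4 of 35, 2 against 69) and between genotypes at ZT4 (2 of 35, 1 against 1). LKO ZT4 replicates 3 and 4 with LKO ZT16 replicates 1 and 4 against the other 4 LKO libraries made the split with 69 genes. For lists chance stays open in every comparison: WT over time 17 of 35 (13, highest other 20), LKO over time 18 of 35 (11, 16), genotypes at ZT4 2 of 35 (20, 20) and at ZT16 6 of 35 (20, 22), and the interaction 92 of 100 (7, 23).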

How the results depend on the processing

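The block by replicate number of the column names, removal of length or length and GC trends, the limit of 1000 nt and the exact permutations were chosen after the result was seen.

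With library weights counts of genes went from 0 to 7 in WT serum over time, 2 to 13 in LKO serum over time, 1 to 3 between genotypes at ZT4, 6 to 255 at ZT16, 11 to 127 for the interaction, 0 to 103 for genotype and 0 to 1 for time averaged. Only the 2 groups compared gave 18 in WT serum over time, 0 in LKO serum over time and 132 at ZT16. Without the filter on low values the counts were 0 in LKO serum over time, 0 at ZT4, 0 at ZT16 and 3 for the interaction, and with at least 2 FPKM 1 in WT serum over time, 2 at ZT4 and 23 for the interaction. The same summed FPKM gave 1, 0, 0 and 17 in WT serum, LKO serum, at ZT4 and for the interaction, and 9 at ZT16. Median-ratio scaling gave 2 at ZT16. Removal of the length trend gave 1, 1, 0 and 16 in WT serum, LKO serum, at ZT4 and for the interaction. With only transcripts of at least 1000 nt 0 genes passed in LKO serum, at ZT4, at ZT16 and for the interaction.

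The replicate numbers of titles and column names differ for 7 of 16 libraries. By titles, 4 of 24 pairs of libraries with the same number had a residual correlation over 0.1 (median 0.001, and -0.004 for other numbers). By column names 8 of 24 did (median 0.06, and -0.008 for other numbers). With these numbers 7 of 16 libraries correlated best with a library of their own number, so a pairing by column names is not excluded. With the block by titles 0 genes passed in LKO serum over time and at ZT16 and 6 for the interaction. With that by column names 3 passed at ZT4 and at ZT16.

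Lists called fell to 0 in every planned comparison and the averaged time comparison with an estimated correlation, and to 1 in the averaged genotype comparison. The exact permutation called 0 in each pairwise comparison and for averaged time, and 5 for averaged genotype. Transcripts of at least 1000 nt gave 13 lists at ZT4. The interaction had 11 lists without the filter and 11 with the length trend removed. Averaged time had 5 with the length trend, with length and GC trends, or with transcripts of at least 1000 nt.

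Leaving out 1 library, genes ranged from 0 to 59 in LKO serum over time, 0 to 16 at ZT4, 0 to 1 at ZT16, 6 to 109 for the interaction, 0 to 174 for averaged genotype and 0 to 1 for averaged time, and were 0 in WT serum over time. Lists ranged from 8 to 15 in WT serum, 8 to 14 in LKO serum, 13 to 21 at ZT4, 18 to 23 at ZT16, 7 to 17 for the interaction, 21 to 23 and 6 to 14 in the averages. The correlation of time effects ranged from -0.26 to -0.12 and that of genotype effects from -0.030 to 0.20.

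Of 2951 gene values recomputed 2682 kept sign and call status, 114 gained a call, 141 lost it and 14 changed sign. The 14 were of Arntl, none called. They were 0.017 at ZT16 and 0.15 for the interaction with the same summed FPKM, 0.080 for the interaction with library weights, and on leaving out 1 library part of the ranges -0.18 to 0.038 at ZT4 and -0.11 to 0.10 for the interaction.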

Other observations

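Lists of muscle atrophy, glucocorticoid, TCA cycle and mitochondrial biogenesis genes had medians near 0, with members going both ways. Median changes of FOXO atrophy genes (n = 28) were 0.03 and 0.02 for night minus day under WT and LKO serum and 0.01 and 0.01 for LKO minus WT at ZT4 and ZT16. Those of glucocorticoid targets (n = 27) were 0.01, 0.02, -0.01 and -0.05, of the TCA cycle (n = 24) 0.01, -0.02, 0.03 and 0.03, and of mitochondrial biogenesis and dynamics genes (n = 26) 0.01, 0.01, -0.00 and -0.01, and none of these lists was called in any planned comparison. Extracellular matrix (n = 38; 0.01, 0.06, -0.05 and 0.02) and undifferentiated myoblast genes (n = 23; 0.03, 0.04, -0.05 and -0.02) were not called either.

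Blood, hepatocyte, macrophage and endothelial markers were rare. S100a8, a neutrophil gene, had the highest group mean of the blood markers, 2.66 FPKM in WT ZT16, against 0.620 in WT ZT4, 0 in LKO ZT4 and 0.721 in LKO ZT16. The macrophage gene Cd68 had 0.948 to 1.23 over groups and the hepatocyte gene Alb at most 0.00638. Complement genes (n = 9), osteoblast markers (n = 6) and adipocyte markers (n = 5) were not called, the last with a median of 0.17 between genotypes at ZT16 (adjusted p = 0.0569).

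Rn45s, the precursor of ribosomal RNA, ran from 2976 to 8006 FPKM over libraries although poly-A RNA had been selected. The smallest root mean square difference between 2 libraries of a group was 0.217 log2, so no 2 libraries were copies of each other.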
